A study of Mus musculus with 2 samples.

How the data were processed

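Ribosome-bound RNA was measured in 1 SFB-positive and 1 SFB-negative library from C57BL/6 mice 6 to 8 weeks old, grouped by the source label of each sample. The sample titles also carry a number beside Ct, 20 for the SFB-positive and 35 for the SFB-negative library, whose meaning the labels do not give. Per the labels, ribosomes tagged with EGFP in villin Cre mice were precipitated with a rabbit antibody against GFP and the RNA was sequenced with Illumina chemistry. Per the submitters' processing notes, TopHat2 and the mouse genome mm9 were used, and other steps are not given in the sources used here. Per the file headers, the authors deposited FPKM per gene in a Cufflinks gene tracking layout, with a lower and an upper bound and a status for each gene. The deposited FPKM of genes marked OK in both libraries sum on average to 4483 times 1000000 per library, so their library denominator is far smaller than the mapped fragments, and the values compare the libraries only up to that denominator.

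Both tables have 23700 rows. The SFB-negative rows held 25 gene symbols turned into dates, which were restored by locus, and values of 1000000 or more are rounded to 3 digits. Rows not marked OK in either library were left out of the comparisons: 304 rows, of which 32 had a value. Rows of the same symbol were summed, which gave 23072 genes. Start positions are counted from 0 in the files and are printed counted from 1. A comparison with RefSeq gene lengths of the reference table bears on this, since end minus start equals the gene length in 8626 genes and end minus start plus 1 in 524. No mitochondrial genes are in the tables.

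The authors' bounds lie 2 standard errors from the value, so the squared ratio of value to standard error gives the number of fragments behind it. This number was whole, within 0.05, for 93.8% of SFB-positive and 91.4% of SFB-negative rows of up to 100 fragments. The fragments sum to 334392 and 659481. For rounded values the fragments were taken from the value and the fragments per FPKM of the same row in the SFB-positive table, times 1.762, the ratio of fragments per FPKM between the tables. The median gene with a fragment had 8 fragments in the SFB-positive and 14 in the SFB-negative library, and the 100 highest genes held 24.9% and 25.9% of all fragments. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

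Values were divided by the same constant, 4483, in both libraries, which makes the libraries sum to 1000000 on average and leaves their ratio as deposited. Log2 ratios were taken with a pseudocount of 1 on that scale, which understates the change of low genes. Ratios printed with intervals are of FPKM without a pseudocount, and their exact Clopper-Pearson intervals come from the fragments. With 1 library per group there is no test, and genes were counted by a fixed 2-fold rule. The design fixed before the data were examined named a filter of 1 FPKM, which here admits nearly every gene with a fragment. The filter that the same design gives for counts, 20 or more summed over both libraries, was used in its place, a choice made after seeing the data, and both counts are printed. This left 6401 genes. Counting noise was simulated 1000 times with every gene at the all-gene ratio. Pooled ratios of lists use the fragments of all members.

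Named genes followed a rule fixed before the data were examined, except for its filter. The rule named the 15 highest and 15 lowest log2 ratios, leaving out models without a symbol, predicted genes named Gm with a number, RIKEN clone names and small RNA genes. It also named up to 4 members of each list with the largest log2 ratio in size, the Saa genes, and Vil1, Rpl10a, Epcam and Cdh1. For the highest and lowest genes it gave a filter of 5 FPKM in the higher library. Its filter for counts, 50 or more summed fragments, was used in its place, a choice made after seeing the data. Other list members named as familiar examples were chosen after their values were seen. The 34 gene lists were fixed beforehand, and each list with 5 or more compared members was placed among 10000 random lists of the same size matched on mean level in 20 bins. The lists for liver sinusoidal endothelium, Kupffer cells, hepatocytes, and intestinal vessels and stroma were written after the highest genes had been seen. Of their members, 6 of 24, 6 of 13, 4 of 31 and 9 of 20 also belong to a list fixed beforehand. Alternatives covered the pseudocount, the scaling, the filter, the fold threshold, repeated symbols and the matching of random lists.

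The steps were tested on simulated data for the SFB-positive against SFB-negative comparison with 6398 genes. Of simulated values, 99.9% gave back their fragments. The simulated bounds were built with the same formula that was then inverted, so this checks the code and not the reading of the authors' bounds. The rounding of SFB-negative values to 3 digits was not simulated. The 2-fold rule relative to the median was passed by 44% of 100 genes changed 2-fold, by 97% of 100 genes changed 4-fold and by 3.36% of 6198 unchanged genes. The simulated counts held counting noise only. In the data, squared deviations from the all-gene ratio averaged 1.41 times counting noise, so these shares are for a quieter setting. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.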

Results

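The series compared RNA bound to ribosomes of the small-intestinal epithelium with and without segmented filamentous bacteria (SFB), gut bacteria that attach to the epithelium of the ileum. The mice carried villin Cre and a ribosomal protein L10 fused to EGFP, so that an antibody against GFP pulls down ribosomes of cells in which the Cre was active, together with the RNA on them. The sequenced RNA was the precipitate from the epithelial fraction released with EDTA. There was 1 SFB-positive library and 1 SFB-negative library, so no difference between them has a replicate check, and no test or p-value is given. The deposited values were FPKM per gene for 23072 genes. In all, 334392 fragments lay behind the SFB-positive values and 659481 behind the SFB-negative values, as read from the authors' error bounds. At least 10 fragments were found for 5510 genes in the SFB-positive library and for 7131 in the SFB-negative library. Every ratio below is SFB-positive over SFB-negative on the deposited FPKM scale, and every interval is an exact 95% binomial interval that covers counting error only. The median ratio of all 6401 compared genes was 0.904, and this value, not 1, is the centre against which single ratios are read.

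The libraries differed little in the epithelial genes. The epithelial marker Vil1, which encodes villin, had 1314 fragments in the SFB-positive and 2487 in the SFB-negative library, a ratio of 0.931 (0.870 to 0.996), whose interval includes the all-gene ratio. The adhesion molecule Epcam had a ratio of 0.879 (0.789 to 0.978) and E-cadherin (Cdh1) 0.923 (0.830 to 1.03). Scaling by the median ratio, total fragments or summed values moves every gene alike and put Vil1 and Cdh1 slightly above 1. Rpl10a was listed at 0 in both libraries, as were Gapdh, Ppia and 30 of 83 ribosomal protein symbols, so a listed 0 is not read as absence here. Across the compared genes, log2 values correlated between the libraries with Pearson's r of 0.950 and Spearman's rho of 0.933, and genes are not independent replicates. Among the 100 genes with at least 1000 fragments over both libraries, the median deviation from the all-gene ratio was 1.06-fold, with a variance 2.77 times that of counting noise.

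Serum amyloid A, the secreted acute-phase protein named in the series title, had almost no fragments in these libraries. Saa1 (mm9, chromosome 7, 53995869 to 53998350) had 2 fragments in the SFB-positive and 0 in the SFB-negative library, which leaves a ratio of 0.331 or more with no upper limit. Saa2 (chromosome 7, 54007203 to 54009684), Saa3 (chromosome 7, 53967368 to 53971046) and Saa4 were listed at 0 in both libraries. Saa1 and Saa2 are near-identical copies whose reads can be split or lost in counting. Genes such as Gapdh were listed at 0 as well, so these values show neither absence nor presence of a difference. How much of the RNA came from the ileum, where SFB attach, was not tested.

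Antimicrobial and oxidant response genes of the epithelium had a pooled ratio slightly below the all-gene ratio of 0.904. Their fragments, 3427 against 7004, gave 0.862 (0.828 to 0.898). All 12 compared members lay within 2-fold, and 2 of them lay above the all-gene ratio. The C-type lectins Reg3b and Reg3g had ratios of 0.932 (0.796 to 1.09) and 0.869 (0.754 to 1.00), and the related Reg3a 0.703 (0.419 to 1.15), with the limit that reads of this family can be shared. Nos2, the inducible nitric oxide synthase, had 82 and 191 fragments and a ratio of 0.757 (0.577 to 0.985). The hydrogen peroxide-producing oxidase Duox2 had a ratio of 0.868 (0.636 to 1.17), and Pigr, the receptor that carries IgA across the epithelium, 0.858 (0.813 to 0.906). Pigr alone gave 1979 of the list's 3427 fragments in the SFB-positive and 4065 of its 7004 in the SFB-negative library. The pooled ratio of the list therefore largely follows this gene. The list's median ratio of 0.869 stood at the percentile of 42.1 among 10000 random lists of the same size and expression level, as a description of these libraries.

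Genes of the IL-22 receptor and the STAT3 response had a pooled ratio of 0.910 (0.825 to 1.00), with 13 of 14 compared members within 2-fold. Il22ra1, the IL-22-binding chain of the receptor, had 104 and 282 fragments and a ratio of 0.650 (0.514 to 0.817), below the all-gene ratio. Tifa, an adaptor of NF-kB signalling, was higher in the SFB-positive library, with 26 and 24 fragments and a ratio of 1.91 (1.05 to 3.47). Cebpd, a transcription factor of the acute-phase response, was the member beyond 2-fold, with 2 and 18 fragments and a ratio of 0.196 (0.0220 to 0.818). Stat3 itself had a ratio of 1.19 (0.857 to 1.65). The list's median stood at percentile 76.5. Of 7 compared chemokines and cytokines, Cxcl16 exceeded 2-fold, with 17 and 13 fragments and a ratio of 2.17 (0.993 to 4.86). The interferon response list had a pooled ratio of 0.993 (0.840 to 1.17) and the MHC class I list 0.973 (0.915 to 1.03).

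MHC class II genes, which present peptides to CD4 T cells, were higher in the SFB-positive library. All 7 compared members lay above the all-gene ratio, all within 2-fold, and the pooled ratio was 1.46 (1.29 to 1.65) from 470 and 569 fragments. H2-Aa had a ratio of 1.97 (1.27 to 3.06), H2-Eb1 1.80 (1.18 to 2.74) and the invariant chain Cd74 1.46 (1.22 to 1.76). The list's median stood at percentile 100 of the random lists. Myeloid and vascular markers were higher in the same library. Myeloid markers had a pooled ratio of 1.67 (1.37 to 2.04), with the mannose receptor Mrc1 at 1.99 (1.31 to 3.03) and the complement gene C1qb at 2.29 (0.928 to 5.84), and their median stood at percentile 99.99. Stromal and vascular markers had a pooled ratio of 1.51 (1.19 to 1.92), with the endothelial cadherin Cdh5 at 2.08 (1.22 to 3.57) and the matrix protein Sparc at 0.801 (0.447 to 1.39). T cell and intraepithelial lymphocyte markers had a pooled ratio of 1.07 (0.877 to 1.30), and among them Cd7 was lower, with 8 and 37 fragments and a ratio of 0.381 (0.153 to 0.831). Only 1 of the B and plasma cell markers was compared, and their pooled ratio was 1.03 (0.685 to 1.53).

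Genes known from liver sinusoidal endothelium led the differences toward the SFB-positive library, in lists written after the highest genes had been seen. These genes had 870 fragments in the SFB-positive and 669 in the SFB-negative library, a pooled ratio of 2.29 (2.07 to 2.54), and all 17 compared members lay above the all-gene ratio. Genes of Kupffer cells, the liver macrophages, had a pooled ratio of 2.37 (1.75 to 3.22), and hepatocyte genes 2.07 (1.80 to 2.38). Without Alb and Serpina1e, which are among the 15 highest genes below, the hepatocyte genes had 1.87 (1.58 to 2.22). Apoe alone gave 116 of their 285 fragments in the SFB-positive and 107 of their 268 in the SFB-negative library. Myeloid markers outside these liver lists had a pooled ratio of 1.37 (1.03 to 1.82), and stromal and vascular markers outside them 1.07 (0.723 to 1.56). Of the 15 highest genes with at least 50 fragments over both libraries, 10 belonged to the liver lists. Igfbp7, a secreted insulin-like growth factor binding protein of vessel walls, was the highest, with 37 and 19 fragments and a ratio of 3.43 (1.92 to 6.32). The secreted nuclease Dnase1l3 had 77 and 45 fragments, and the endothelial receptor phosphatase Ptprb 114 and 67. The scavenger receptor Stab1 had a ratio of 2.24 (1.66 to 3.04), the receptor Gpr182 2.64 (1.45 to 4.91), the VEGF-C receptor Flt4 2.61 (1.53 to 4.52) and serum albumin (Alb) 2.51 (1.88 to 3.36). The other members of the 15 were Lifr, Gpr116, Serpina1e, Rgl2, Ltbp4, Plxnd1, Ehd3 and coagulation factor F8.

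**Figure D1:**
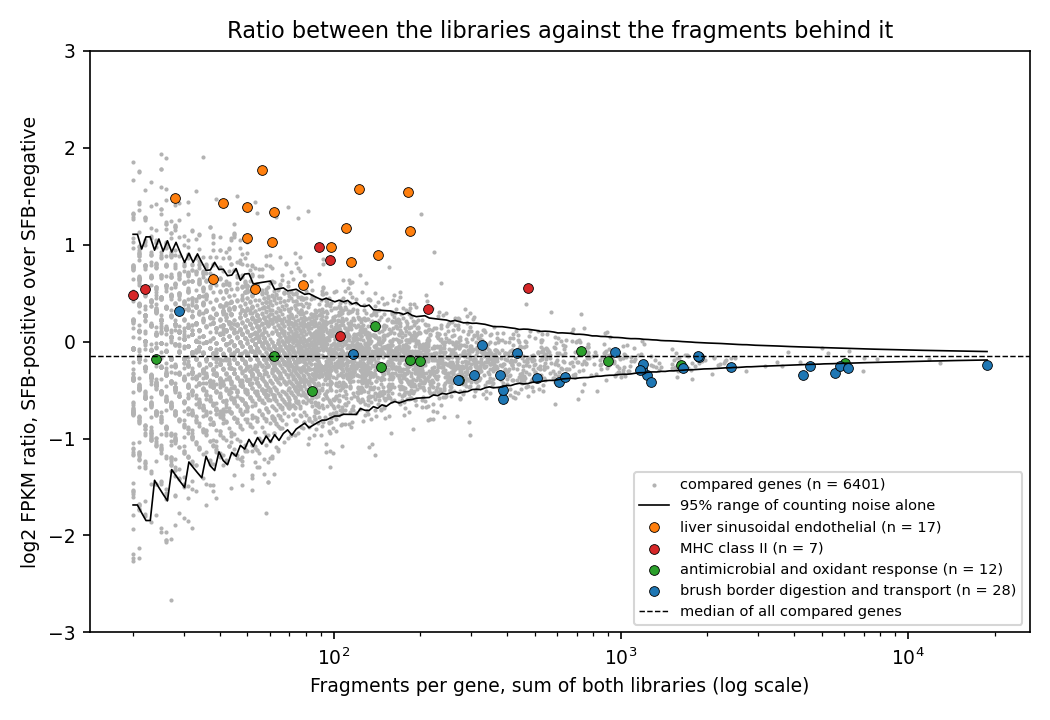
Log2 FPKM ratio of the SFB-positive over the SFB-negative library for each of 6401 compared genes, against the gene's fragments summed over both libraries on a log scale; the lines enclose 95% of counting noise alone around the median of all genes (dashed, log2 of -0.15). Genes of liver sinusoidal endothelium and MHC class II genes lie above the median, and brush border genes lie mostly below it.

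The 15 lowest genes, clone and predicted gene names left out, belonged to none of the lists. Zfand5, a zinc finger protein of protein degradation, had 8 and 44 fragments and a ratio of 0.320 (0.130 to 0.688). Cct3, a subunit of the cytosolic chaperonin, and the lysosomal transporter Slc46a3 both had 10 and 49 fragments and a ratio of 0.360 (0.162 to 0.719). Rragc, a GTPase of amino acid sensing, and the mitochondrial fusion protein Mfn1 had a ratio of 0.369 (0.158 to 0.767). Acsf2, an acyl-CoA synthetase, had 18 and 79 fragments and a ratio of 0.402 (0.226 to 0.676). The others were Carhsp1, Tmem104, Plekha5, Ppp2r5b, Fam78a, Asxl1, Gdpd5, C78339 and Wbp1. The RIKEN clone gene 2610301G19Rik, which the naming rule leaves out, was lower than all of them, with 8 and 50 fragments and a ratio of 0.282 (0.115 to 0.599).

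**Figure D2:**
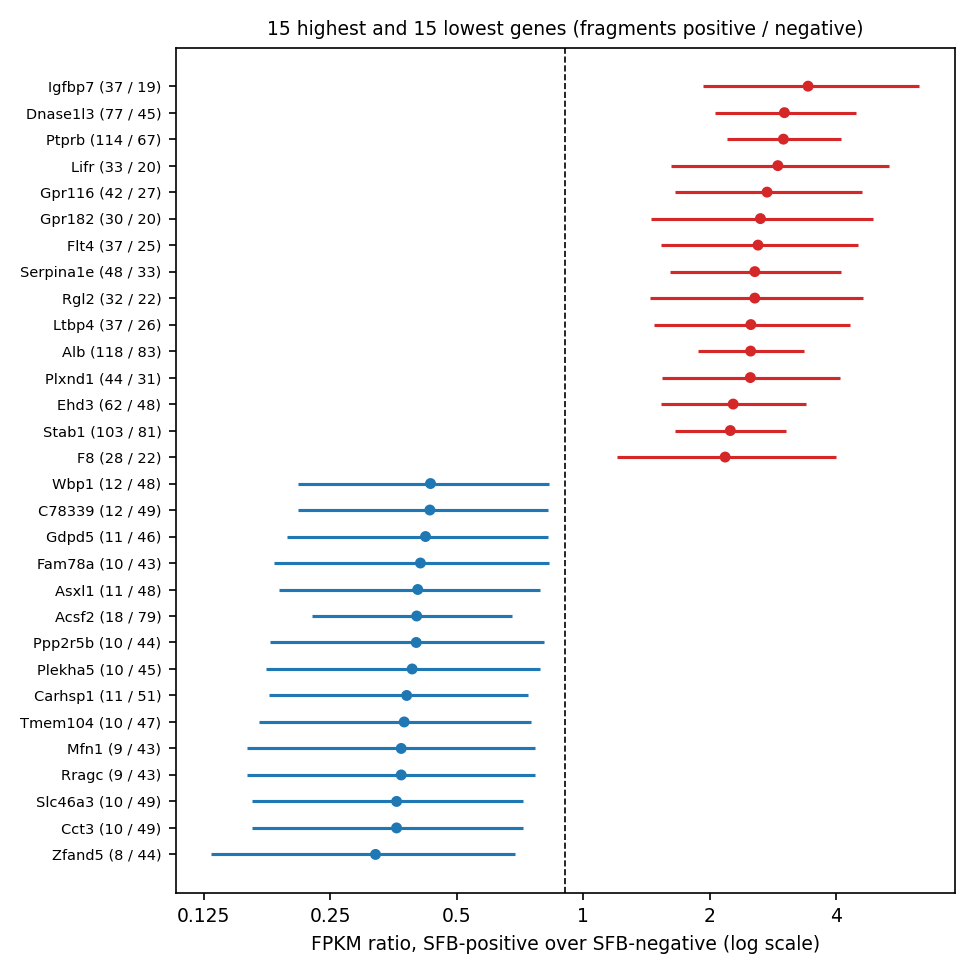
FPKM ratio of the SFB-positive over the SFB-negative library on a log scale for the 15 highest and 15 lowest genes with at least 50 fragments over both libraries, clone and predicted gene names left out; bars are exact 95% counting intervals, the dashed line is the all-gene ratio of 0.904, and fragments per library stand beside each symbol. Of the genes drawn, Igfbp7 is highest at 3.43 and Zfand5 lowest at 0.320.

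At 2-fold or more, 109 of the 6401 compared genes were higher and 244 lower in the SFB-positive library. Counting noise alone around the all-gene ratio gave 38 higher (25 to 51 in 95% of 1000 simulations) and 214 lower (188 to 244). Without the liver and vessel lists, 91 genes were higher and 244 lower. The authors' own error bounds did not overlap for 27 of the higher and 66 of the lower genes. The split depended on the scaling of the libraries: 30.9% of these genes were higher on the deposited scale, 52.7% (178 higher, 160 lower) after scaling by the median ratio, 32.9% (114 and 233) by the upper quartile, 54.4% (180 and 151) by total fragments and 54.1% (179 and 152) by summed values. The filter fixed beforehand, a value of 1 or more in either library, admits nearly every gene with a fragment (12868 of 13036) and gave 1511 higher and 1972 lower.

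Genes of nutrient digestion and transport at the brush border were slightly lower in the SFB-positive library relative to other genes. The pooled ratio of this list was 0.829 (0.816 to 0.843) from 20612 and 43792 fragments, 5 of 28 compared members lay above the all-gene ratio, and all 28 were within 2-fold. The amino acid transporter subunit Slc3a1 had a ratio of 0.661 (0.523 to 0.829), the amino acid transporter Slc7a7 0.705 (0.560 to 0.882), the glucose transporter Slc5a1 0.785 (0.736 to 0.838) and aminopeptidase N (Anpep) 0.844 (0.819 to 0.870). The list's median stood at percentile 0.75 among random lists matched on expression level. Against unmatched random lists it stood at 4.8, inside the central 95%. Xenobiotic metabolism genes had a pooled ratio of 0.826 (0.787 to 0.866) and a percentile of 0.325, with 5 of 26 compared members above the all-gene ratio. Their log2 median relative to all genes was -0.19, and -0.0788 at a minimum of 100 fragments, an alternative chosen after seeing the data. Among them the cytochrome P450 Cyp3a25 had a ratio of 0.646 (0.453 to 0.910) and the glutathione transferase Gsta4 0.619 (0.346 to 1.06).

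**Figure D3:**
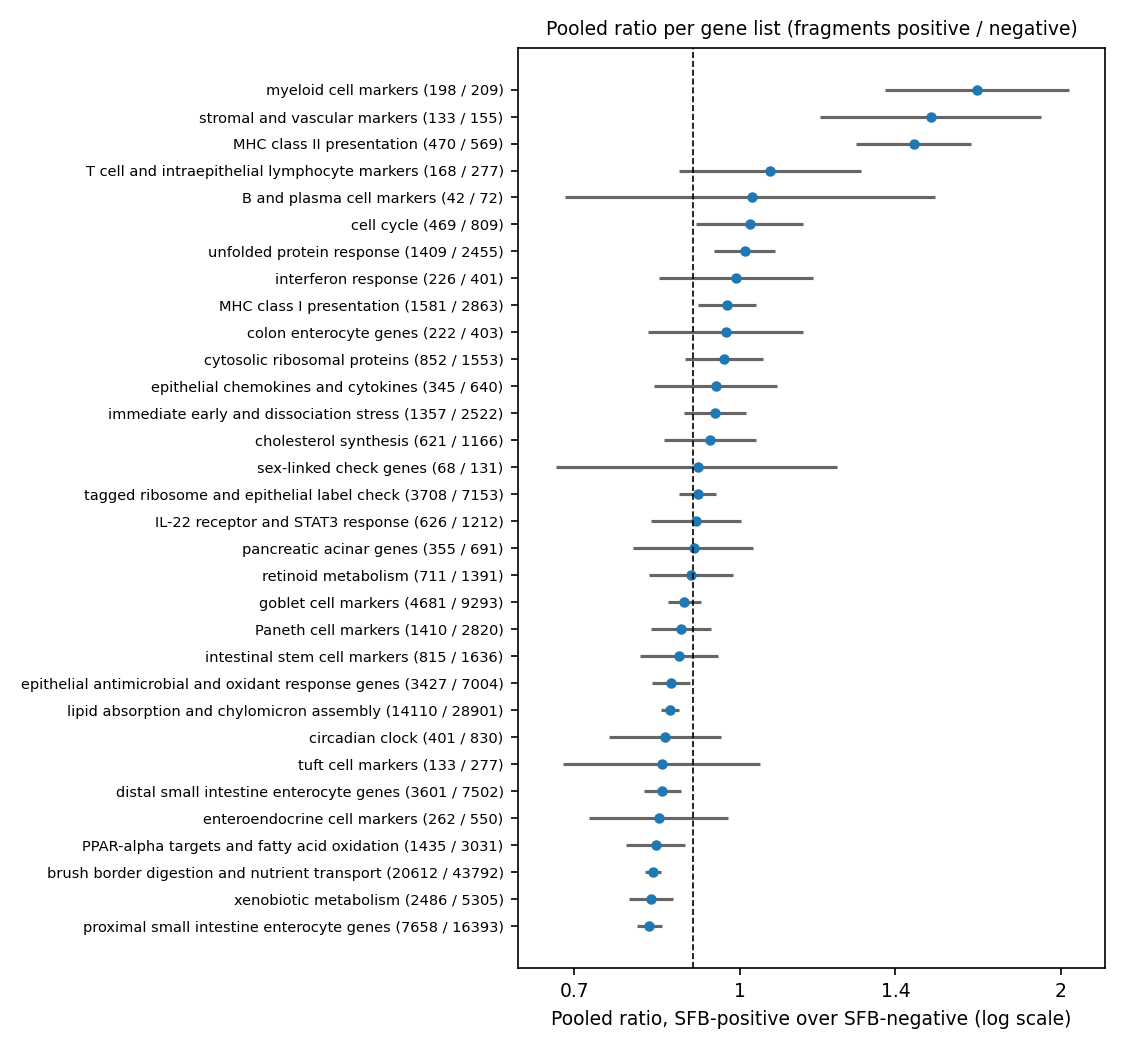
Pooled ratio of the SFB-positive over the SFB-negative library on a log scale for each gene list fixed beforehand with at least 20 fragments; points are ratios of summed fragments, bars exact 95% counting intervals, the dashed line the all-gene ratio, and fragments per library stand beside each list. Myeloid markers (1.67), stromal and vascular markers (1.51) and MHC class II genes (1.46) lie above all other lists.

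Unfolded protein response genes lay slightly above other genes, with 15 of 19 compared members above the all-gene ratio, a pooled ratio of 1.01 (0.947 to 1.08) and a median at percentile 97.54. In this list the stress-induced membrane protein Herpud1 had a ratio of 1.43 (1.04 to 1.95) and the disulfide isomerase Pdia6 1.56 (1.06 to 2.29). Colon enterocyte genes stood at percentile 98.65 with 5 members compared, but their pooled ratio of 0.971 (0.820 to 1.15) includes the all-gene ratio. Their highest compared member was Slc37a2, with 12 and 13 fragments and a ratio of 1.63 (0.678 to 3.87). Their log2 median above that of all genes, 0.39, shrank to 0.0322 with no filter, 0.0274 at a value of 1 or more and 0.0158 at 5 or more. Both lists fell inside the central 95% of unmatched random lists, at 87.83 and 96.22. Of 28 lists with at least 5 compared members, 6 stood outside the central 95% of matched random lists, against 1.4 if all were random. They were MHC class II, myeloid, brush border, xenobiotic, unfolded protein response and colon enterocyte genes.

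Markers of the specialised epithelial cells stayed inside that range. Paneth cell markers had a pooled ratio of 0.881 (0.826 to 0.940), goblet cell markers 0.888 (0.857 to 0.920), enteroendocrine markers 0.840 (0.722 to 0.974), tuft cell markers 0.846 (0.683 to 1.04) and stem cell markers 0.878 (0.806 to 0.955). Fcgbp alone gave 3941 of the 4681 goblet list fragments in the SFB-positive and 7874 of the 9293 in the SFB-negative library. Single members beyond 2-fold rested on few fragments. The stem cell receptor Lgr5 had 4 and 21 fragments and a ratio of 0.336 (0.0838 to 0.995), the tuft cell channel Trpm5 had 4 and 17, and the goblet cell gene Tmed3 had 8 and 30. Cell cycle genes had a pooled ratio of 1.02 (0.910 to 1.15) and a percentile of 92.6. Enterocyte genes of the proximal small intestine had a pooled ratio of 0.823 (0.801 to 0.846), at percentile 13.8. Those of the distal small intestine had 0.846 (0.813 to 0.880), at percentile 5.75. The proximal gene Lct had 1476 and 3090 fragments. Of the distal list, Fabp6 had 20 and 29 and Slc10a2 had 2 and 8, while Naaladl1 had 860 and 1869. The share of ileal RNA in these libraries was not tested.

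Lists of lipid, sterol, fatty acid and retinoid metabolism also stayed inside the range. Pooled ratios were 0.860 (0.843 to 0.878) for lipid absorption, 0.939 (0.850 to 1.04) for cholesterol synthesis, 0.834 (0.783 to 0.889) for PPAR-alpha targets and fatty acid oxidation, and 0.901 (0.822 to 0.987) for retinoid metabolism. In cholesterol synthesis, lanosterol synthase (Lss) had 12 and 8 fragments and a ratio of 2.64 (0.994 to 7.46), while the later enzymes Ebp and Nsdhl had ratios of 0.496 (0.208 to 1.06) and 0.493 (0.180 to 1.17). Immediate early genes had a pooled ratio of 0.948 (0.887 to 1.01) and a percentile of 97.0, with Nr4a1 at 2.06 (0.883 to 4.87). The pooled ratio was 0.851 (0.754 to 0.960) for circadian clock genes and 0.967 (0.888 to 1.05) for cytosolic ribosomal proteins. The pancreatic acinar list was carried by Zg16, a gene also on the goblet list, with 331 of its 355 fragments in the SFB-positive and 646 of its 691 in the SFB-negative library. The other 24 acinar genes had 24 and 45 fragments together. The X-linked Xist had a ratio of 0.880 (0.643 to 1.19), and the Y-linked Ddx3y had 2 and 3 fragments.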

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

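The choice of these genes followed a rule, and no test was run on them. Rows that the authors marked as having too little data were left out of the comparisons, yet 5 of their genes had fragments above the limit of 3 that a count of 0 allows. Defa6, a Paneth cell defensin whose reads can be shared with related defensins, had 55 fragments in the SFB-positive and 96 in the SFB-negative library, a ratio of 1.02 (95% counting interval 0.711 to 1.42). Tgoln2, a protein of the trans-Golgi network, had 26 and 46 fragments and a ratio of 1.02 (0.591 to 1.65). The predicted gene Gm5506 had 48 and 79 fragments, and the pseudogenes Pisd-ps3 and Rplp2-ps1 had 11 and 26, and 13 and 21. All 5 intervals include the all-gene ratio of 0.904.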

How the results depend on the processing

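Scaling by total fragments or summed values, the minimum of 100 fragments, keeping genes marked as low data, a pseudocount on the deposited scale and leaving out the liver lists were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Genes 2-fold higher and lower, 109 and 244 here, numbered 70 and 160 with pseudocount 5, 178 and 160 scaled by the median ratio, 180 and 151 by total fragments, and 179 and 152 by summed values; the last 3 scalings moved the all-gene log2 median from -0.15 to -0.000282, 0.0145 and 0.0107. They numbered 1511 and 1972 with no filter (13036 genes) and at 1 or more (12868 genes), 1042 and 1151 at 5 or more (10864 genes), 395 and 858 at 1.5-fold, 1 and 12 at 4-fold, and 5 and 4 at a minimum of 100 fragments (2117 genes). The Vil1 log2 ratio turned from -0.10 to 0.0447 scaled by the median ratio, 0.0595 by total fragments and 0.0557 by summed values, since these scalings shift every gene alike. List medians relative to all genes (log2) moved with no filter, at 1 or more and at 5 or more: chemokines to 0.71, 0.71 and 0.80, interferon response to 0.35, 0.35 and 0.34, colon to 0.0322, 0.0274 and 0.0158, T cell markers to 0.76, 0.76 and 0.75. A minimum of 100 fragments gave 0.15 for Paneth, -0.0788 for xenobiotic and 0.29 for ribosomal protein genes. Against unmatched random lists, percentiles moved to 97.94 for cell cycle, 96.22 for colon, 4.8 for brush border and 87.83 for unfolded protein response genes. In the other runs 374 list medians stayed within the spread of random lists, 24 percentiles on their side of the central 95%, and 1761 values of named genes within their counting intervals. For the other changes the cause was not tested, except that the filters and the minimum change which genes enter. Depth limits genes below about 50 fragments, where 95% of log2 deviations spanned -1.30 to 1.26.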

Other observations

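All tests in this part were chosen after the results were seen, as were the genes named in the next paragraph.

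Some genes with many fragments departed from the all-gene ratio of 0.904 within lists whose medians stayed inside the central 95% of random lists. The classical MHC class I gene H2-D1 had 296 and 427 fragments and a ratio of 1.22 (95% counting interval 1.05 to 1.42). H2-K1, another classical class I gene, had 0.946 (0.823 to 1.09), with the limit that reads of this family can be shared. Acadvl, the enzyme that starts the oxidation of very long chain fatty acids in mitochondria, had 35 and 105 fragments and a ratio of 0.587 (0.389 to 0.869). Among all compared genes, 3 were listed at 0 in 1 library, which is not read as absence here. Mea1 had 21 and Zbtb17 had 23 fragments in the SFB-negative library, and Tor1aip1 had 21 in the SFB-positive library.

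Genes known from liver sinusoidal endothelium had fragments in both libraries and were higher in the SFB-positive library, at 2.29 pooled. The 16 members outside the 15 highest genes had 1.97 (1.70 to 2.28). This is no independent check, since the list was written after the highest genes had been seen. Among these 16, Fcgr2b at 2.85 and Oit3 at 2.75 had too few fragments to be ranked for the 15. Gene length does not account for the higher ratios. The central 95% of random lists of other genes matched on transcript length and level ended at a median ratio of 1.06. The 12 detected genes of intestinal vessels and stroma had 0.0524 (0.0290 to 0.0875) of the fragments per gene of these 16. That cannot decide on intestinal vessels as the source, since the 16 include Cdh5, Kdr and Pecam1. The list of stromal and vascular markers holds these genes too. Hepatocyte genes had 0.518 (0.462 to 0.581) of the sinusoidal fragments in the SFB-positive library, with Alb at 118, so they did not lead the liver lists. That cannot decide on whole liver as the source. No liver profile was compared, and abundant genes such as Gapdh were listed at 0 in both libraries. A candidate source is RNA or reads of a liver endothelial preparation, which would bring Kupffer cell and hepatocyte genes along. With members among the 15 highest left out, the smaller lower bound of their pooled ratios was 1.58, above the all-gene ratio. That bound is of the hepatocyte genes, with 116 of 285 SFB-positive fragments from Apoe. Whole liver would bring the same genes along, so this bound cannot tell it from an endothelial preparation. The Kupffer cell and hepatocyte lists were also written after the highest genes had been seen. The EDTA fraction and the pull-down from villin Cre cells would both lower the share of RNA from liver cells. Neither step kept out all RNA of other cells. The T cell list markers Cd3e and Gzma had 18 and 45, and 15 and 26 fragments. Whether RNA of liver cells entered, and at which stage, was not tested.

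MHC class II genes were higher in the SFB-positive library, and both sinusoidal endothelium and Kupffer cells are known to express them. Whether a liver source, if present, was their only source was not settled. Myeloid markers outside the liver lists were higher too, at a pooled ratio of 1.37 (1.03 to 1.82). Myeloid cells of the intestine as a source of MHC class II fragments were not tested. With counting intervals widened by the spread between genes, the pooled MHC class II ratio was 1.46 (1.26 to 1.69). The sinusoidal genes outside the 15 highest had 1.97 (1.65 to 2.35). The ratio of 1.46 lay below the second interval, while the 2 intervals overlapped, and overlap is not a test of a difference. A mixture of epithelial transcripts with a larger share from such a source in the SFB-positive library may also give such a ratio and was not tested. SFB colonization cannot be told apart from any other difference between the libraries, because there was 1 library per group.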
